A study of Mus musculus with 8 samples.

How the data were processed

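Total RNA from mouse lymph nodes was counted with the NanoString nCounter PanCancer Immune Profiling panel for mouse, per the labels and the series description. In this assay, barcoded probes bind chosen transcripts and are counted one molecule at a time, without amplification. The table holds 770 genes in 8 samples, of which the titles call 4 tumor-free and 4 tumor-bearing, and each title gives a replicate number from 1 to 4. RNA was extracted with a spin-column kit and treated with DNase, per the labels' protocols. The nodes labelled tumor-bearing had received Eµ-myc lymphoma cells through the lymphatic vessels, per the series description. Eµ-myc lymphoma is a mouse B cell tumor driven by a Myc transgene. The labels do not state that the numbered nodes came from separate animals, so p-values measure the spread between these samples, which may include technical spread.

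The deposited values are a normalized count signal on a linear scale, made by the authors, with 2 decimals. The software, the genes used for scaling and any background step are not given in the sources used here. In every column all values lay within 0.1 of a step of a whole multiple of 1 factor per sample, so 100% of values could be turned back into whole counts. The factors ranged from 0.822 to 1.29. The smallest value of a library stood for 1 to 3 counts. A step search starting from the smallest value alone finds the whole counts in 1 column only, labelled tumor-bearing replicate 4, and the other 7 rest on a search over fractions of that value. Recovered totals ranged from 659771 to 819257 counts per library, with a mean of 792137 ± 26613 (SD, n = 4) in the libraries labelled tumor-free and 751239 ± 61570 (SD, n = 4) in those labelled tumor-bearing. A gene at the filter of 20 thus rests on about that many counts. How many of them come from the target is not known, since no background step is given and 0 genes read 0. Libraries of 1 group differed from each other by more than sampling noise (chi-square per degree of freedom from 3.48 to 316), so no column is a copy of another, but this does not tell separate nodes from repeat runs of 1 RNA.

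Genes were kept where the deposited value was 20 or more in at least 4 samples, which left 609 genes and removed 161. Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over the kept genes and a threshold of 0.05. All 8 samples entered 1 fit with the group as its only term. Differences are labelled tumor-bearing minus labelled tumor-free, and a fold change on this scale understates the change of low genes. Confidence intervals are at 95%. The 30 lists of cell type and pathway genes held 534 genes, of which 422 were measured, with symbols matched without regard to case. For each list the number of called members, the median change and limma's camera test against the rest of the panel were computed, with a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry were run beside it. The 28 lists with 3 or more kept members were tested. A list score is the mean log2(value + 1) of the kept members in 1 library.

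Genes are named by a rule. It takes the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap and whose higher group has a mean of at least 50. It also takes up to 3 called members of each list with the largest change. Where fewer than 2 are called, the uncalled members with the largest change fill the list up to 2. A preset group of 32 genes, 31 of them measured, is named whatever the values. Reference genes are given as a group. Some genes that the rule takes are not reported here, and they stay in every fit, list and test while being left out of the counts over named genes. Where 5 or fewer members of a list were called in a direction, those the rule does not reach are named too, and these were chosen after their values were seen: Fcer2a, Blk, Btk, Fasl, Lgals3, Cd84, Csf1r, Emr1, Clec4a2, Pecam1, Cxcr4, Cxcl16, Ccl12, Bcl2, Atm, Bid, Cd55 and Tgfbr1. Groups, tests, lists, this rule and the alternatives were set before the data were examined, except where a choice is said to come later. The alternatives were 3 other scalings, 2 other pseudocounts, 2 other filters, limma without trend, with robust moderation, with sample weights and with a replicate block, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered counts, leaving out each replicate, a plain per-gene test and stricter thresholds. Scaling to the same total was added after seeing the data.

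The fits were tested on simulated data with the 609 kept genes, counts drawn around the real means, and 200 genes changed. limma recovered 7.5% of genes changed 1.5-fold, 43.3% of those changed 2-fold and 93.9% of those changed 4-fold, and called 0.2% of unchanged genes. edgeR recovered 14.9%, 58.2% and 97.0%, and DESeq2 17.9%, 65.7% and 97.0%. Camera called the planted list and 0 of 20 lists of unchanged genes. Each gene was drawn independently here, whereas the real pan T cell list had an estimated correlation of 0.954 between its genes. The simulation thus does not show how often camera with the preset correlation calls unchanged lists of correlated genes. Rises and falls were also planted in equal numbers, and no simulated library lay between the groups. The recovery rates and the share of unchanged genes called thus do not carry over to the real gene calls. Gene symbols are those of the table. Of the 770, 754 stood in a RefSeq table of the mouse assembly GRCm38.p6, 2 more matched apart from case, 8 matched a synonym and 6 did not match. No coordinates are given, since no build belongs to the probes in the sources used here.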

Results

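The transcripts of immune and malignant cells were counted in mouse inguinal lymph nodes, in 4 libraries labelled tumor-free and 4 labelled tumor-bearing. The series description asks which transcripts go with malignant and immune cells in nodes holding lymphoma cells that spread through the lymphatics. Each library held between 659771 and 819257 recovered counts over 770 genes. The 10 most abundant genes took from 28.2% to 38.1% of the counts of a library.

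Myc, the oncogene whose transgene drives this lymphoma, was read in every library before any other gene. In the libraries labelled tumor-free its deposited values were 29389, 31449, 9249.5 and 33147 for replicates 1 to 4. In the libraries labelled tumor-bearing they were 3147, 2996, 3281 and 3090.1. Mean Myc was thus 25809 ± 11146 (SD, n = 4) in the nodes labelled tumor-free and 3129 ± 119 (SD, n = 4) in the nodes labelled tumor-bearing, a log2 difference of -2.88 (SE 0.38, limma adjusted p = 0.00987). Myc took from 1.13% to 4.88% of all recovered counts in the libraries labelled tumor-free and from 0.310% to 0.448% in those labelled tumor-bearing. This runs against the labels for a tumor driven by Myc. Groups are therefore called by their labels throughout, every direction below depends on those labels, and each signed value changes sign if the labels are exchanged.

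**Figure D1:**
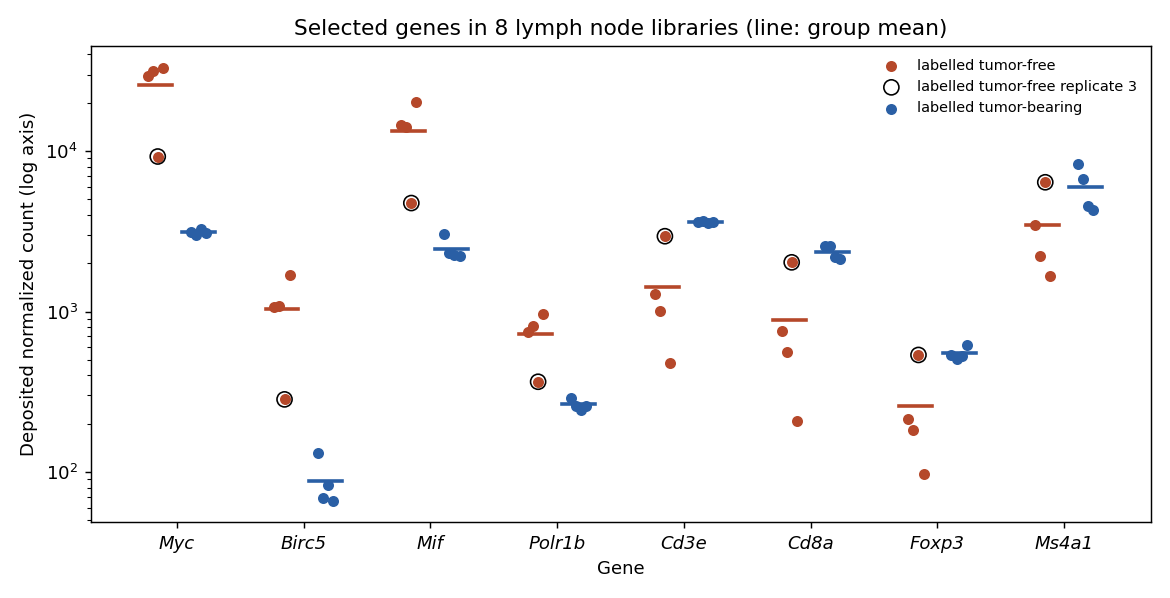
Deposited normalized count (log axis) of 8 genes in each library, with a line at each group mean and a ring around labelled tumor-free replicate 3. Every library labelled tumor-free, from 9249.5 to 33147, lies above every library labelled tumor-bearing in Myc, while Cd3e lies below.

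Of the 609 genes kept, 168 were higher and 65 lower in the nodes labelled tumor-bearing at an adjusted p under 0.05 (limma). The largest falls were those of Thbd, Birc5 and Myc and the largest rises those of Il22ra2 and Il17rb, among genes whose groups did not overlap and whose higher mean was at least 50. The 4 values of one group all lay beyond the 4 of the other in 194 of the 609 kept genes, where chance gives 2.86% for a single gene. Many kept genes moved together (74.0% of the variance on the first principal component), so these are not separate events. Among the 233 called genes the groups were apart in 166, a share raised in advance because calls rest on the same difference. Of the called genes, 127 were at least 2-fold higher and 42 at least 2-fold lower. The adjusted p of called genes ran from 0.00987 to 0.0492, so that small changes in the data moved many of them across the threshold. Without labelled tumor-bearing replicate 3, limma called 0 genes higher and 0 lower, against 220 and 66 at an unadjusted p under 0.05, where edgeR on all samples called 117 and 143 and DESeq2 157 and 181 after adjustment. Without labelled tumor-free replicate 1 the counts were 5 higher and 20 lower, without replicate 2 they were 0 and 5 (165 and 73 unadjusted), without replicate 3 they were 264 and 93, and without replicate 4 they were 89 and 52. Without labelled tumor-bearing replicate 1 the counts were 11 and 49, without replicate 2 they were 1 and 11, and without replicate 4 they were 1 and 5.

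The median log2 difference of the kept genes was 0.36 in the deposited values. It was 0.91 when libraries were scaled on the reference genes, -0.17 when they were scaled to the same median, 0.09 after quantile normalization, 0.22 with the same total (a scaling added after seeing the data), 0.03 with edgeR and -0.0043 with DESeq2. The share of called genes that were higher was 72.1% in the deposited values, 90.5% after reference-gene scaling, 43.2% with the same median, 59.5% after quantile normalization, 45.0% with edgeR and 46.4% with DESeq2. The balance of rises and falls thus depends on the scaling, also within limma. For that reason each list is also compared with the rest of the panel, a difference that does not move with 1 factor per library.

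Birc5, Mif, C1qbp, Tfrc and Vegfa were lower in the nodes labelled tumor-bearing together with Myc. Birc5, an inhibitor of apoptosis made in dividing cells, was 10.1-fold higher in the nodes labelled tumor-free (log2 difference -3.34, SE 0.50, limma adjusted p = 0.00987). It averaged 1030 ± 578 there and 87.7 ± 30.4 in the other group (SD, n = 4 each), and it was the single kept gene of the cell cycle list, which had 2 of 20 genes measured. Mif, a cytokine, and C1qbp, a mitochondrial protein, fell by 2.28 and 2.27 on the log2 scale (adjusted p = 0.0149 and 0.0131, limma). Tfrc, the transferrin receptor that brings iron into growing cells, fell by 2.24 (adjusted p = 0.018). The vascular growth factors Vegfa and Vegfc fell by 2.68 and 2.59, and Thbd, thrombomodulin, fell by 3.34. The chemokine Ccl2, the interferon-induced Ifitm1, the complement protease C1ra and the transcription factor Cebpb complete the 12 largest falls, with log2 differences of -2.52, -2.23, -2.19 and -1.96. Myc and Birc5 were not called without labelled tumor-bearing replicate 3, where both had an adjusted p of 0.0513, nor by the plain per-gene test, whose smallest adjusted p over all genes was 0.0664.

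The panel's reference genes, chosen for even expression, were not even here. Of 20, 8 were lower and 0 higher, with the same counts adjusted over the list alone, and their median log2 difference was -0.51, which turned to 0.04 under the scaling that uses these genes themselves. The largest changes were in Polr1b, a subunit of RNA polymerase I, at -1.37 (adjusted p = 0.0195), Eef1g, a translation elongation factor, at -1.30 (adjusted p = 0.0195) and Gusb at -1.18 (adjusted p = 0.0253, limma). Camera called the list lower than the rest of the panel (difference in mean log2 change -0.85, adjusted p = 5.99e-06), and with an estimated correlation the adjusted p = 0.812.

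T cell genes were higher in the nodes labelled tumor-bearing throughout their list. All 19 kept genes of the pan T cell list were called higher, also when adjusted over the list alone, with a median log2 difference of 1.60. Cd3e, a chain of the T cell receptor complex, averaged 1429 ± 1067 in the nodes labelled tumor-free and 3601 ± 35.9 in those labelled tumor-bearing (SD, n = 4 each), a log2 difference of 1.63 (SE 0.45, adjusted p = 0.0261). Cd2 rose by 2.15, Thy1 by 1.70 and Cd4 by 1.49. The list lay 1.37 above the rest of the panel (camera adjusted p = 7.42e-05), and with an estimated correlation of 0.954 between its genes the adjusted p = 0.812. Cd3e was no longer called in 6 of the 8 fits without 1 library, with adjusted p from 0.0536 to 0.0816 in those fits.

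Cytotoxic and natural killer genes leaned the same way with fewer calls. Of 12 kept genes of the CD8 T cell and cytotoxic list, 5 were called higher and 0 lower, the same adjusted over the list alone. Cd8a rose by 1.85 (SE 0.55, adjusted p = 0.0286), the cathepsin Ctsw by 1.94, Cd8b1 by 1.56, perforin, Prf1, by 1.42 and Fasl by 1.20. Granzyme B, Gzmb, stood at 43.1 ± 22.6 and 51.9 ± 44.3 in the nodes labelled tumor-free and tumor-bearing (SD, n = 4 each; log2 difference 0.11, adjusted p = 0.859), a difference that turned negative under 9 alternatives. Interferon gamma, Ifng, lay below the filter, at 13.1 ± 6.4 and 26.3 ± 25.6. Of 15 natural killer genes, 3 were called higher, Klrd1 by 1.69 and Klra17 by 1.06 on the log2 scale and Cd160 2.83-fold, the same adjusted over the list alone, while Ncr1 had a log2 difference of 1.25 (adjusted p = 0.0624). Camera called neither list in the deposited values (adjusted p = 0.0653 and 0.136, and 0.812 and 0.815 with an estimated correlation), but with the preset correlation it called the CD8 T cell and cytotoxic list with the same median (adjusted p = 0.028), quantile normalization (0.0171), the same total (0.0457), a replicate block (0.0421), edgeR (0.041) and without labelled tumor-free replicate 1 (0.0424), and the natural killer list with the same median (0.028). After reference-gene scaling 10 and 12 genes of these lists were higher, and with edgeR 1 and 3.

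Of the regulatory T cell, inhibitory checkpoint and costimulation lists, 9 of 11, 9 of 17 and 8 of 11 kept genes were called higher in the nodes labelled tumor-bearing. The checkpoint gene Lgals3 was called lower (-0.75). After reference-gene scaling 10, 15 and 11 genes of these lists were higher, and with edgeR 3, 7 and 5. Foxp3, the defining factor of regulatory T cells, rose by 1.36 (SE 0.44, adjusted p = 0.035), from 257 ± 193 to 547 ± 46.5 (SD, n = 4 each). Called regulatory T cell genes, 10 when adjusted over the list alone, included Ikzf2 at 1.47 and Icos at 1.40. Called checkpoint genes, 11 higher and 1 lower when adjusted over the list alone, included Cd96 and Cd200r1 at 1.66 each. Called costimulation genes, 9 when adjusted over the list alone, included Cd40lg at 1.68, Cd27 at 1.62 and Cd28 at 1.45. These lists share members with each other (Icos, Ctla4, Tnfrsf4 and Tnfrsf18) and with the pan T cell list (Cd96, Cd27 and Cd28), so their calls are not separate findings. Camera called all 3 lists higher than the rest of the panel (adjusted p = 0.0356, 0.0426 and 0.0356), and with an estimated correlation each had an adjusted p = 0.812. None of the 3 was called after reference-gene scaling (adjusted p = 0.145 each), with the filter at 100 (0.0799 each) or without labelled tumor-bearing replicate 4 (0.0535 each), and costimulation was also not called without a filter (0.0602).

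The series title speaks of an immunosuppressive environment, and the preset genes of immune suppression behaved unevenly. Ctla4 and Pdcd1, receptors that restrain T cells, rose by 1.14 (adjusted p = 0.0324) and 1.01 (adjusted p = 0.0299). Lag3 had a log2 difference of 0.67 (adjusted p = 0.0506), Cd274, the ligand of Pdcd1, of 0.78 (adjusted p = 0.133), Havcr2 of 0.61 (adjusted p = 0.0925), Tigit of 0.15 (adjusted p = 0.685), Tgfb1 of 0.24 (adjusted p = 0.244) and Nos2 of 0.16 (adjusted p = 0.636). Tigit, Tgfb1 and Nos2 turned negative with the same median, edgeR and DESeq2, and Tigit and Tgfb1 also after quantile normalization. Il10, Ido1 and Arg1 lay below the filter, with means from 9.5 to 16.3 in both groups. Foxp3 was not called in 7 of the 8 fits without 1 library, and the pan T cell score was higher in each library labelled tumor-bearing than in any labelled tumor-free.

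**Figure D2:**
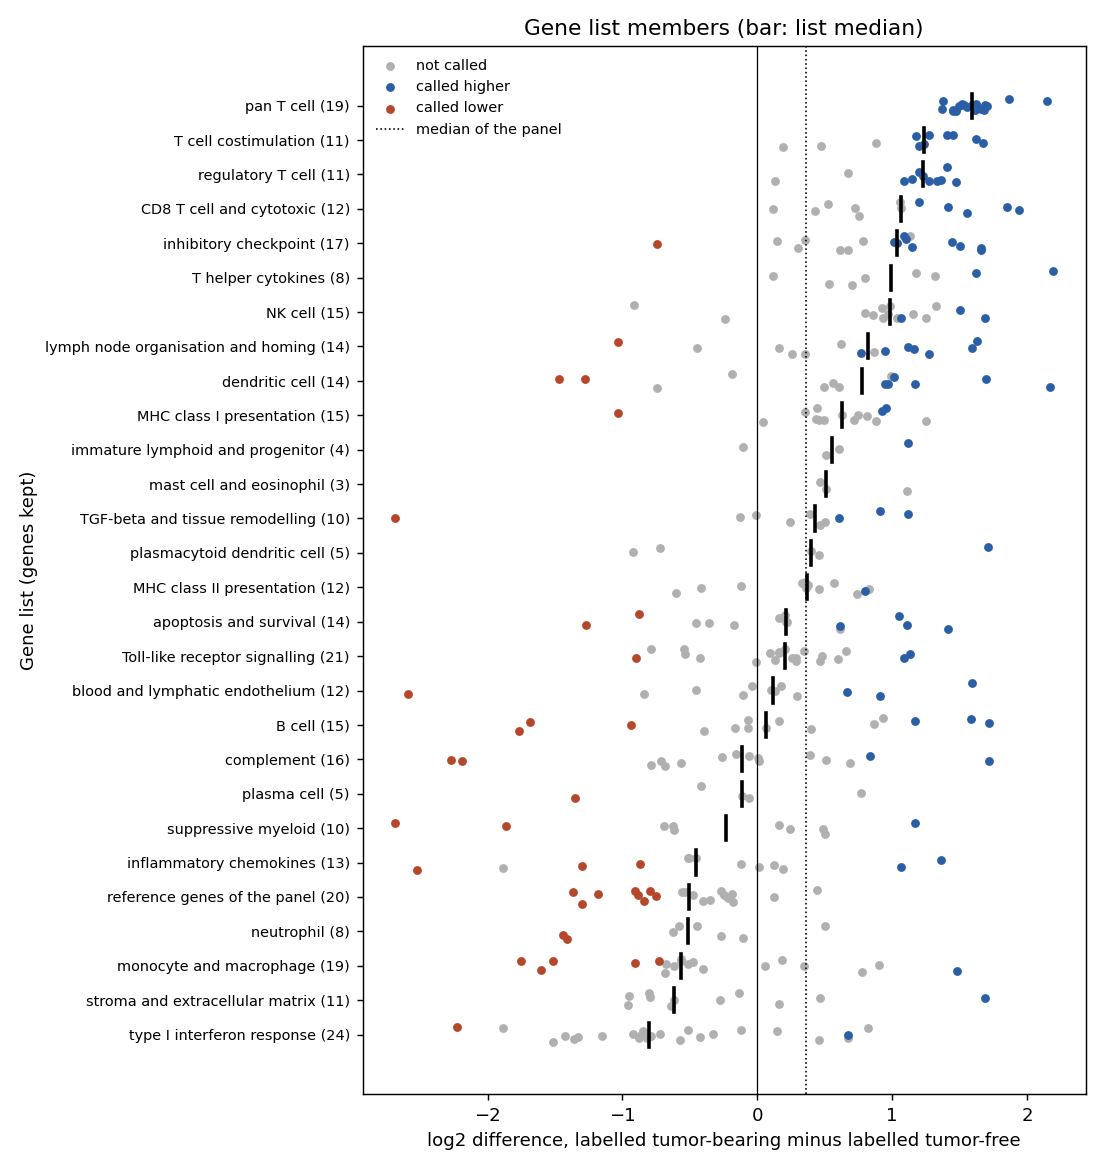
Log2 difference, labelled tumor-bearing minus labelled tumor-free, of each kept gene of the 28 tested lists, with a bar at the list median and a dotted line at the panel median of 0.36. The pan T cell genes all lie to the right of it, with a median of 1.60, and the interferon list has the lowest median, -0.80, which stayed negative under each scaling.

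Of the 12 largest rises, that of Il22ra2, a soluble receptor for interleukin 22, was 2.32 (SE 0.40, adjusted p = 0.0149), from 14.0 ± 5.7 to 76.5 ± 31.8 (SD, n = 4 each). Il17rb rose by 2.20, the integrin Itgae by 2.17, Il23r by 2.09, the chemokine receptor Cxcr6 by 2.00, Hsd11b1 by 1.93 and Il18r1 by 1.87. Of 8 T helper cytokine genes, 2 were called higher, among them Gata3 (1.62), the same adjusted over the list alone, and camera did not call the list (adjusted p = 0.136).

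B cell genes moved in both directions. Of 15, 3 were called higher and 3 lower, the same adjusted over the list alone, and the list median was 0.07, which turned negative with the same median, quantile normalization, the same total, edgeR and DESeq2 and rose to 0.61 after reference-gene scaling, with 8 genes higher and 2 lower. Pou2af1, a B cell coactivator, fell by 1.77 (SE 0.37, adjusted p = 0.0195) and the adaptor Blnk by 1.69 (adjusted p = 0.0156), while Cr2, a complement receptor of mature B cells, rose by 1.72 (adjusted p = 0.0253). The other called members were Fcer2a (1.58), Blk (1.17) and Btk (-0.94). Ms4a1 had a log2 difference of 0.93 (adjusted p = 0.0861). Camera did not call the list (adjusted p = 0.513), and its mean of 0.12 was positive while the difference from the rest of the panel was -0.16. Among 5 plasma cell genes, 1 was called, Irf4, which fell by 1.35 (limma adjusted p = 0.0233), and among 4 progenitor genes, Il7r rose by 1.12 (limma adjusted p = 0.0253). The counts were the same adjusted over the list alone, with no camera call (adjusted p = 0.265 and 0.513). Il7r, at 1034, 961, 2242 and 789 in replicates 1 to 4 labelled tumor-free, had the same order of libraries as Cd3e. Its rise thus cannot be told from that of the T cell genes. Plasma cell genes lower numbered 2 with the same median and with quantile normalization, 3 with edgeR and 4 with DESeq2, with 0 higher in each. After reference-gene scaling 1 plasma cell gene was higher and 1 lower, and 3 progenitor genes were higher. Prdm1 and Flt3 had log2 differences of 0.77 (adjusted p = 0.0609) and 0.61 (adjusted p = 0.0663).

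The macrophage and neutrophil lists lay below the rest of the panel in the nodes labelled tumor-bearing (camera adjusted p = 0.00263 and 0.0356, and adjusted p = 0.812 each with an estimated correlation). Of 19 monocyte and macrophage genes, 5 were called lower and 1 higher, the same adjusted over the list alone. The number lower was 13 with the same median and with edgeR and 14 with DESeq2, each with 1 higher, and after reference-gene scaling 3 were lower and 4 higher. The Fc receptor Fcgr1 fell by 1.75 (SE 0.33, adjusted p = 0.0173), from 110 ± 27.1 to 33.3 ± 14.6 (SD, n = 4 each), and the scavenger receptors Marco and Msr1 by 1.60 and 1.52. Emr1 and Csf1r fell by 0.91 and 0.73, and Cd84 rose by 1.48. Cd68 and Itgam had log2 differences of -0.52 (adjusted p = 0.0925) and -0.57 (adjusted p = 0.0952), and Cd68 turned positive after reference-gene scaling. The list differed from the rest of the panel by -0.68, and its call was lost with the filter at 100 (difference -0.54, adjusted p = 0.0799). Of 8 neutrophil genes, 2 were called lower, Fcgr4 at -1.44 and Fpr2 at -1.41, the same adjusted over the list alone, while the list median of -0.51 turned to 0.01 after reference-gene scaling. The neutrophil call was lost with the same median (adjusted p = 0.0557), without labelled tumor-free replicate 2 (0.0826) and without labelled tumor-bearing replicate 4 (0.0535).

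Chemokines and the remaining myeloid lists were mixed. Of 13 inflammatory chemokines, 3 were called lower, Ccl2, Ccl7 (-1.30) and Ccl12 (-0.87), and 2 higher, Cxcl16 (1.07) and Ccl5 (1.36), a product of T and natural killer cells, the same adjusted over the list alone. Camera called that list lower (adjusted p = 0.0487), with an estimated correlation the adjusted p = 0.812, and the call was lost under 13 of its 22 alternatives, while its median of -0.45 turned to 0.07 after reference-gene scaling. Among the 22, the settings without trend and with robust moderation could not change the camera result. Of 10 suppressive myeloid genes, 2 were called lower, Vegfa and Chil3 (-1.86), and 1 higher, Il4ra (1.17), the same adjusted over the list alone (camera adjusted p = 0.195). Of 14 dendritic cell genes, 6 were called higher and 2 lower, 7 and 2 adjusted over the list alone, with Itgae, Ccl22 (1.70) and Clec4n (-1.47) the farthest and Clec4a2 (-1.28) also lower (camera adjusted p = 0.527). The dendritic cell list had 10 higher and 2 lower after reference-gene scaling and 4 and 3 with the same median, and the suppressive myeloid list 5 and 2 and 1 and 4. Itgae is also carried by T cells. Itgax, the dendritic cell integrin, had a log2 difference of 0.56 (adjusted p = 0.0913). Of 5 plasmacytoid dendritic cell genes, Ccr9 was called, at 1.71, and Bst2 had a log2 difference of -0.92 (adjusted p = 0.0787), the same adjusted over the list alone (camera adjusted p = 0.854). In replicates 1 to 4 labelled tumor-free, Ccr9 was 273, 237, 865 and 138 and Il4ra 848.5, 684, 1357 and 451. Cd3e had the same order of libraries (1291, 1001, 2947 and 477). The rises of Ccr9 and Il4ra thus cannot be told from that of the T cell genes.

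Genes of node structure and homing held calls in both directions. Of 14 genes of lymph node organisation and homing, 7 were called higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.265). Cxcr4 was the lower gene (-1.03). Lta, lymphotoxin alpha, rose by 1.63, the vessel mucin Glycam1 by 1.59, Tnfsf11 by 1.27, Ccr7, which guides T and dendritic cells into the node, by 0.95 and its ligand Ccl21a by 0.77 (adjusted p = 0.0271). Ccl19 and Cxcl13 had log2 differences of 0.36 (adjusted p = 0.419) and 0.62 (adjusted p = 0.238), and Ccl19 turned negative with the same median, edgeR and DESeq2. Of 12 endothelial genes, 3 were called higher, Glycam1, Eng (0.91) and Pecam1 (0.66), and 1 lower, Vegfc, the same adjusted over the list alone (camera adjusted p = 0.614). The homing list had 11 higher and 0 lower after reference-gene scaling and 3 and 2 with edgeR, and the endothelial list 5 and 1 after reference-gene scaling, 1 and 1 with the same median and 0 and 1 with edgeR, its median of 0.12 turning to -0.42 with the same median. Lyve1, a lymphatic vessel marker, had a log2 difference of -0.84 (adjusted p = 0.195). Of 11 stromal genes, 1 was called, Itgb3, at 1.69, and Fn1 had -0.96 (adjusted p = 0.0606), the same adjusted over the list alone (camera adjusted p = 0.129), and camera called the list lower without a filter (adjusted p = 0.039), while with an estimated correlation the list had an adjusted p = 0.812 in the main fit.

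The interferon list lay below the rest of the panel in the nodes labelled tumor-bearing, a difference of -0.98 (camera adjusted p = 0.00179), and with an estimated correlation of 0.749 between its genes the adjusted p = 0.812. The 24 kept genes had a median log2 difference of -0.80, yet 1 was called lower, Ifitm1, and 1 higher, Ifi27 (0.67, adjusted p = 0.0492), and 1 lower and 0 higher adjusted over the list alone. The number lower was 16 with the same median, 11 with quantile normalization and with edgeR, 18 with DESeq2, 6 with the same total and 1 after reference-gene scaling, with 0 or 1 higher in each. Against no change, fry gave an unadjusted p = 0.352 for the list. The list score of the libraries labelled tumor-free was 9.96, 8.61, 9.21 and 7.93, and that of the libraries labelled tumor-bearing 9.26, 8.23, 7.90 and 7.67. Ifitm1 did not follow this score within the libraries labelled tumor-free, at 157, 316, 78.5 and 422 for replicates 1 to 4. Its fall thus does not stand for the list. Of 15 genes of MHC class I presentation, 2 were called higher, Cd1d1 (0.95) and Cd1d2 (0.93), and 1 lower, Psmb7 (-1.04), and 0 and 1 adjusted over the list alone (camera adjusted p = 0.284). Of 12 genes of MHC class II presentation, Ciita, their master regulator, was called, at 0.80 (adjusted p = 0.0443), and 0 adjusted over the list alone, while H2-Ob had 0.83 (adjusted p = 0.06; camera adjusted p = 0.795).

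**Figure D3:**
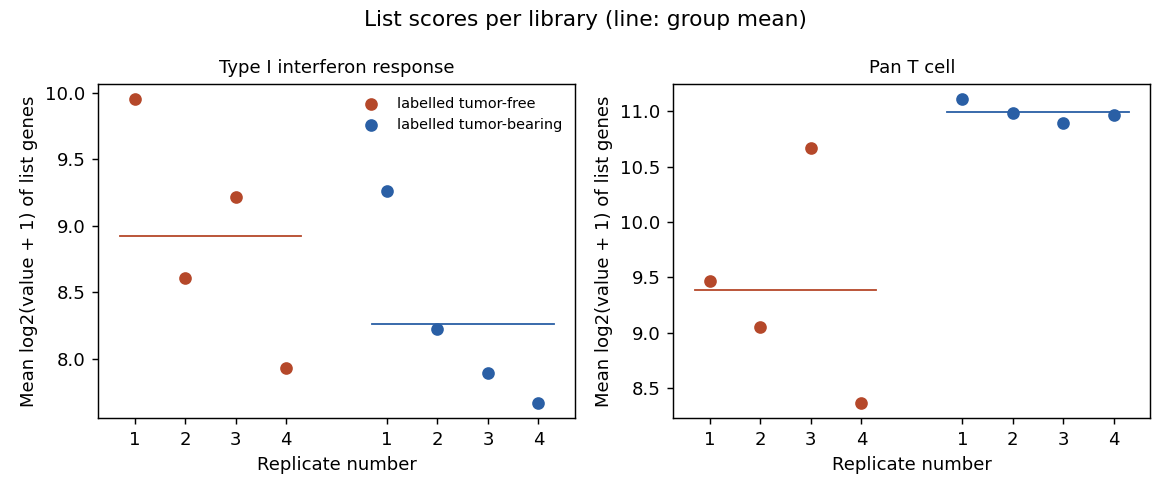
Mean log2(value + 1) of the interferon list and of the pan T cell list in each library, with a line at each group mean. Interferon scores run from 7.93 to 9.96 in the libraries labelled tumor-free, and the pan T cell score of labelled tumor-free replicate 3, at 10.67, lies near the libraries labelled tumor-bearing.

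The libraries labelled tumor-bearing resembled each other closely and those labelled tumor-free did not. Correlations across genes, which are not independent replicates, ran from 0.981 to 0.993 within the former group, from 0.873 to 0.982 within the latter and from 0.824 to 0.983 between groups. The first principal component held 74.0% of the variance and the next 14.9%. Labelled tumor-free replicate 3 lay at 5.62 on the first component, the other libraries of its label from -24.54 to -10.88 and the libraries labelled tumor-bearing from 10.02 to 13.13. Its mean correlation was 0.922 with its own label and 0.973 with the other. In Myc, at 9249.5, it lay above all libraries labelled tumor-bearing, and its pan T cell score of 10.67 lay below all of theirs, which ran from 10.89 to 11.11.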

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

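Of 308 comparisons of 4 libraries of 1 group, for each gene named here and each list score on the log2 scale, 16 had a library far from its nearest neighbour (Dixon's ratio above its 95% critical value), where chance gives about 1 in 20, so the number alone says little. Both tests on labelled tumor-free replicate 3 below were chosen after its values were seen.

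In labelled tumor-free replicate 3, Myc was 9249.5, against 29389 to 33147 in the other libraries of its label. In the same library Blnk was 1835, against 3858 to 4275, Ccl2 was 84.6, against 134 to 145, and Clec4a2 was 35.7, against 64.1 to 66.4. It was high in Il22ra2, at 22.4 against 10.6 to 11.5, in Ifi27, at 1071 against 680 to 711, and in Bcl2, at 353 against 177 to 195.

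In labelled tumor-bearing replicate 1, Mif was 3041, against 2233 to 2309, Fcgr4 was 59.5, against 22.8 to 26.3, and Ifng was 64.6, against 12.1 to 14.3. Glycam1 was 796 there, against 1013 to 1063. Bst2 was 2654 in labelled tumor-free replicate 1, against 1074 to 1213. In labelled tumor-free replicate 4, Fn1 was 156, against 55.0 to 64.1, and Cd68 was 398, against 270.3 to 281. Epcam was 170.1 in labelled tumor-bearing replicate 2, against 47.8 to 56.9, and Tnfrsf10b was 60.2 in labelled tumor-bearing replicate 3, against 75.0 to 76.8.

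Labelled tumor-free replicate 3 lay between the groups. On a scale where 0 is the mean of the libraries labelled tumor-bearing and 1 that of the other 3 labelled tumor-free, its median over 239 genes with at least a 2-fold difference was 0.211 (quartiles 0.141 and 0.328), and Myc stood at 0.217. A library wholly of the other group is argued against, since at 59.7% or more of such genes it lay beyond 3 libraries labelled tumor-bearing on the tumor-free side, where a library labelled tumor-bearing did so at 13.0% to 39.3%, although an earlier version of this test, on the median position alone, did not decide (0.211 against a highest 0.158). A mixture of both kinds of material in this node may explain it, since genes higher in either group gave nearly the same position (0.217 and 0.209, a difference of 0.008). Nearly equal positions do not by themselves show a mixture, since labelled tumor-free replicates 1 and 4 and labelled tumor-bearing replicate 2, which do not lie between the groups, had them too (1.060 and 1.081, 1.484 and 1.502, -0.018 and -0.028). Whether such a mixture arose in the animal or in handling was not tested and stays open.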

How the results depend on the processing

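Fold changes kept their direction more than calls kept their threshold, and the cause was not tested except where named. Of 2648 values of named genes under the alternatives, 1927 kept direction and side of the threshold, 608 lost the call, 85 gained it and 28 turned. Of 613 list values the numbers were 563, 35, 9 and 6. Fits without trend, with robust moderation and with a replicate block leave fold changes unchanged, so no direction could turn in them. Camera was run alike without trend and with robust moderation, so those list values could only stay the same. With an estimated correlation a list could not turn either. Genes higher numbered 363 with reference-gene scaling, 296 with sample weights, and 0 with the per-gene test without moderation (215 higher and 89 lower unadjusted) or at an adjusted p under 0.01 with limma (127 higher and 55 lower at an unadjusted p under 0.01). Genes lower numbered 38 with reference-gene scaling, 151 with the same median, 121 with quantile normalization, 109 with the same total (added after seeing the data), 143 with sample weights, 143 with edgeR, 181 with DESeq2, 42 at 2-fold or more, 5 at an adjusted p under 0.01 and 0 with the per-gene test. Leaving out 1 replicate gave 0 to 264 genes higher and 0 to 93 lower, and 1 to 5 lists higher and 3 to 5 lower, with 1 sample fewer. Against 4 lists higher and 5 lower, reference-gene scaling gave 1 higher, the filter at 100 gave 1 and 2 with fewer genes, the same median gave 6 higher and 3 lower, and camera with an estimated correlation and fry gave 0 in both directions. Unadjusted, the lowest p of camera with an estimated correlation was 0.106, and fry had 9 lists up and 2 down at p under 0.05 (lowest adjusted p = 0.113). Calls within lists moved with the scaling or model: reference-gene scaling gave 11 higher of MHC class I, 9 of MHC class II and 7 of the T helper genes, edgeR 3 higher of the regulatory T cell genes, and DESeq2 6 lower of the stromal genes and 18 lower of the reference genes. Equal replicate numbers did not pair the libraries, except for number 1. Deviations correlated at 0.548, 0.028, 0.014 and -0.037 for numbers 1 to 4, with only number 1 closest to its own partner. Processing shared by equal numbers is not excluded by this, and the interferon score below leaves it open. A replicate block gave 173 genes higher and 65 lower, 207 of the 233 calls among them, and 5 lists higher and 4 lower.

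Values that turned were mostly near 0. With the same median they were -0.026 for Kit, -0.27 for Epcam, -0.39 for Tigit, -0.37 for Nos2, -0.30 for Tgfb1, -0.42 for Gzmb and -0.18 for Ccl19. With edgeR they were -0.21 for Tigit, -0.17 for Nos2, -0.082 for Tgfb1, -0.14 for Gzmb and -0.072 for Ccl19, and with DESeq2 -0.25, -0.20, -0.12, -0.16 and -0.11. Quantile normalization gave -0.046 for Tigit, -0.079 for Tgfb1 and -0.016 for Gzmb, and reference-gene scaling 0.027 for Cd68. Gzmb was -0.029 with the same total and -0.16 with sample weights. Without 1 replicate Gzmb ran from -0.38 to 0.39 (negative without labelled tumor-free replicates 2 and 4 and labelled tumor-bearing replicate 1), Nos2 from -0.026 (without labelled tumor-bearing replicate 1) to 0.29 and Epcam from -0.16 (without labelled tumor-bearing replicate 2) to 0.44. Differences from the rest of the panel turned for the endothelial and TGF-beta lists (0.45 and 0.083 with the filter at 100) and for MHC class II (-0.029 without a filter, -0.067 with the filter at 100). Without 1 replicate they ran from -0.008 to 0.064 for MHC class II and from -0.27 to 0.053 for the plasmacytoid list, turning without labelled tumor-bearing replicate 1 and labelled tumor-free replicate 1. Depth limits genes near the filter of 20, among them Ifng, Il10, Ido1 and Arg1.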

Other observations

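The tests of label exchange, of labelled abundance, of counting depth and of the interferon pattern, and the genes set against the T cell score, were chosen after the values were seen. The test of scaling and the counts over other splits were not.

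Several lists not described above held few calls in the deposited values. Of 14 apoptosis and survival genes, 4 were called higher, Fas (1.41), Tnfrsf10b (1.11), Bcl2 (1.05) and Atm (0.61), and 2 lower, among them Bid (-0.88), the same adjusted over the list alone (camera adjusted p = 0.795). Of 16 complement genes, Cr2 and Cd55 (0.84) were higher and C1qbp and C1ra lower, the same adjusted over the list alone (camera adjusted p = 0.114). Of 21 Toll-like receptor genes, Tlr1 (1.13) and Irak2 (1.09) were higher and Ly86 (-0.90) lower, and 0 of the 21 were called adjusted over the list alone (camera adjusted p = 0.726). Of 10 TGF-beta and remodelling genes, Tgfbr2 (1.12), Runx1 (0.91) and Tgfbr1 (0.61) were higher and Vegfa lower, 4 and 1 adjusted over the list alone (camera adjusted p = 0.673). Of 3 mast cell and eosinophil genes 0 were called, with Il5ra at 1.11 (adjusted p = 0.0585) and Kit at 0.51 (adjusted p = 0.144), and of 2 epithelial genes Cdh1 was higher (1.47, adjusted p = 0.0265) while Epcam had 0.27 (adjusted p = 0.607). These counts depend on the scaling: after reference-gene scaling 13 of the Toll-like receptor genes, 8 of the apoptosis genes, 8 of the TGF-beta genes and 6 of the complement genes were higher, while with the same median 6 complement genes and 5 Toll-like receptor genes were lower. Camera called the complement list lower without labelled tumor-free replicate 3 (adjusted p = 0.043), while with an estimated correlation the list had an adjusted p = 0.812 on all libraries. The medians of the apoptosis and Toll-like receptor lists, 0.21 and 0.20, turned negative with the same median, quantile normalization, edgeR and DESeq2, and both lists lay below the rest of the panel although their medians were positive. The plasmacytoid, endothelial and TGF-beta lists likewise had medians of 0.40, 0.12 and 0.43 and differences from the rest of the panel of -0.09, -0.30 and -0.14, and camera, which uses moderated statistics, put the last of them in the upward direction.

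The T cell score of the same library (the mean of 17 pan T cell genes, without Cd3e and Cd4) was subtracted from 15 chosen genes. All except Cd8a then had lower means in the libraries labelled tumor-bearing, though none passed after adjustment. That count was nearly fixed in advance, since the score itself was higher in the libraries labelled tumor-bearing. A gene at the panel median log2 difference of 0.36 would also come out lower. The share over all kept genes was not computed, so the count says nothing particular about these genes. Other members of the checkpoint list were not tested in this way, among them Cd200r1, whose log2 difference of 1.66 was as large as the pan T cell median of 1.60. Relative to that score Foxp3 was -1.61 ± 0.10 in the libraries labelled tumor-free and -1.85 ± 0.17 in those labelled tumor-bearing (SD, n = 4 each, exact permutation p = 0.0857). The difference was -0.46 for Ctla4, -0.38 for Il2ra, -0.34 for Tnfrsf4, -1.46 for Tigit and -0.82 for Cd274, each with an exact permutation p = 0.0286, the smallest that 70 assignments allow, and 0.0858 after adjustment over the 15 genes tested. For Pdcd1 it was -0.59 (exact permutation p = 0.0571, adjusted 0.0952), for Cd4 -0.11 and for Cd8a 0.24 (exact permutation p = 0.657 and 0.343).

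Myc and Birc5 were higher and T cell genes lower in the nodes labelled tumor-free, the reverse of what the labels lead to for a Myc-driven lymphoma. The authors' scaling is argued against as the cause, since under the reference-gene, median and quantile scalings Myc stayed at -2.34 or lower and called and the pan T cell list stayed called higher with the preset correlation (adjusted p = 0.812 with an estimated correlation in the main fit). Counting depth is argued against too, since mean recovered totals differed by a ratio of 1.05. Which nodes held more lymphoma cells and whether the group labels were exchanged stay open: Myc had a log2 difference of -2.88 (SE 0.38) and its lowest value labelled tumor-free was 2.82 times the highest labelled tumor-bearing, but both values restate the pattern and do not test either explanation. Another unlabelled difference between the nodes also stays open and untested.

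In the deposited values, the interferon score had an SD of 0.86 in the libraries labelled tumor-free and 0.71 in those labelled tumor-bearing (n = 4 each). The mean log2 difference of the list between labels was -0.66 in the deposited values, no larger than this spread. It was -1.21 with the same median and -1.155 with DESeq2. The spread within labels was not computed under those scalings. The Myc level alone did not account for the spread within labels, since labelled tumor-free libraries with Myc within 1.3-fold of each other differed by up to 2.03 in the interferon score. That pair, replicates 1 and 4, also differed in the pan T cell score (9.47 and 8.36). Equal Myc thus does not fix the share of cells, and cell composition stays open as a cause. Processing shared by equal replicate numbers could not be excluded: replicate 1 was high in both groups (1.03 and 1.00 above the group means) and replicate 4 low in both (-0.997 and -0.596), and 0 of the numbers deviated by more than 0.3 in opposite directions, although replicate 3 came close (0.29 and -0.37). With libraries matched by number, the library labelled tumor-bearing had the lower score each time (9.96 and 9.26, 8.61 and 8.23, 9.21 and 7.90, 7.93 and 7.67). Apart from the share of Myc-high cells, no biological explanation was tested.

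Chance is argued against as the source of the gene calls, for a grouping of these libraries only. The real split called 233 genes and the highest of the other splits called 0. Thus 1 of the 35 splits of the 8 samples, the real split itself, gave as many, the lowest share that 35 splits allow. The other splits mix libraries of both labels, which widens their spread. If libraries were repeat runs of 1 RNA, the splits would say nothing about nodes. Chance cannot be excluded for the number of lists called by camera with the preset correlation, since 11 of the 35 splits gave 9 or more lists and the highest other split gave 13.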
